A study of Mus musculus with 9 samples.

How the data were processed

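Whole right lung was removed from BL6 (C57/BL6), FVB/N and SV129 mice, snap frozen and extracted on silica columns, and biotin-labelled target was prepared after the array maker's manual, per the labels' protocols. The deposited values are linear intensity signals, 1 per probe set and array, in a single table for 9 arrays. The software that made these signal values is not given in the sources used here. From the deposited values themselves, each array's intensity had been scaled by the authors to the same mean of 500 after the top and bottom 2% of probe sets were left out, and the arrays had not been quantile normalized. Another 12 arrays are mentioned in the series' design text as having had technical difficulties, and they were not analysed here. No detection calls, scan dates or raw probe values were used here, and no genome was used, so no genomic positions are given.

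Each array's group, strain and array number were taken from its title and its pressure (50 or 85 kPa) and exposure (4 weeks) from its description. All 9 columns were matched to a sample. The choices of design, threshold, gene lists and settings to vary were made before the data were examined.

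Signals were transformed as log2(signal + 16), so fold changes are on that scale and understate the change of dim probe sets. The medians of the arrays then ran from 6.76 to 6.99. Their range of 0.228 exceeded a preset limit of 0.2, so by the preset rule quantile normalization became the main setting. From 45101 probe sets 64 controls were left out, and then the dimmest 40% by mean over the 9 arrays, which left 27022. Of the 45037 probe sets that are not controls, 34945 had 1 gene symbol in the platform's annotation, 932 had several and 9160 had none in the table used. Gene identifiers were matched to a current gene table (99.42% matched), which changed 0 symbols. No gene was named from a probe set with several symbols. A gene was represented by its brightest probe set (18193 genes, 12895 of them past the filter), and other probe sets of a gene were set beside it.

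Models were fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and a Benjamini-Hochberg adjusted p below 0.05 as the threshold. The hypoxia effect across strains and the strain differences came from an additive model of strain and condition over all 9 arrays (5 residual degrees of freedom, prior degrees of freedom 4.14). The effect in each strain and the interaction came from a model with 6 groups (3 residual degrees of freedom), in which the spread comes from the 3 pairs of hypoxic arrays alone. The spread thus also holds any difference that 1 array of a pair carries, such as kidney transcripts.

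Named genes followed a preset rule. For hypoxia they were the 12 largest rises and 12 largest falls among genes past the threshold whose hypoxic arrays all lay on the same side of the normoxic array of their strain. For each strain they were the 5 largest rises and falls past the threshold. For the interaction they were the 10 genes with the smallest p past the threshold. For the strain comparison they were the 4 highest and 4 lowest genes per strain, past the threshold against both other strains, by the smaller of the log2 differences. Where no gene passed, the 5 with the smallest p were given, and members of the gene lists could be named besides.

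The 23 preset lists held hypoxia-inducible factor targets and glycolytic genes, extracellular matrix, smooth muscle, cell cycle, erythroid, endothelial, alveolar type 2, alveolar type 1, airway epithelial, macrophage and dendritic, neutrophil, B cell, T and NK cell, interferon, MHC, circadian clock, immediate early, glucocorticoid and stress, heart and skeletal muscle, adipocyte, BMP and TGF-beta, vascular tone and sex-linked genes. Lists were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry. Lists of 21 tested kidney markers and 8 tested brown adipocyte and fast muscle markers were added after the data had been seen.

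The control transcripts were compared on the deposited scale of signal by a 2-sided exact permutation test of mean log2 values. Settings varied by plan were median centring, pseudocounts of 1 and 64, no filter or a filter of 60%, eBayes without the trend or robust, array weights, each array left out in turn, the array number as a block, 1 probe set per gene, other models and set tests, the 6 hypoxic arrays alone, and the other probe sets of each named gene. Added after the data had been seen were the authors' scaling without quantile normalization, leaving out both arrays with kidney transcripts, and the kidney marker level as a covariate.

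The scripted models were tested on simulated data of 27022 probe sets with 100 changed by 1 and 100 by 2 log2 units. For hypoxia across strains 63 and 97 were recovered with 15 false calls, for hypoxia in BL6 5 and 56 with 8 false calls, and for BL6 against FVB/N 50 and 98 with 18 false calls. In each of these comparisons false calls made up more than the 5% of calls that the threshold aims at. With 1 of 23 lists moved by 0.5 log2 units over 12895 genes, that list and 0 others were called. The noise was drawn independently for each probe set, while in the data the estimated correlation within a list reached 0.689 (heart and skeletal muscle). The simulation thus cannot show how many lists are falsely called where genes vary together. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.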

Results

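Gene expression was measured in whole right lung of mice of 3 strains on 9 one-colour oligonucleotide arrays, each read out as 1 signal value per probe set. BL6, FVB/N and SV129 mice had spent 4 weeks in a chamber at 50 kPa (hypobaric hypoxia, 2 arrays per strain) or at 85 kPa, the pressure of the laboratory's own altitude (here called normoxia, 1 array per strain). The number of arrays limits the precision. The labels do not say that the arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical. Within a strain the lone normoxic array was assumed to vary like the hypoxic ones. Values are log2 signals after quantile normalization, changes are hypoxic minus normoxic, errors are SE for changes and SD for levels, and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless stated otherwise.

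The first comparison asked which transcripts differed between chronically hypoxic and normoxic lung over the 3 strains together. The largest rise among the genes named here was that of Ntrk2, the receptor for brain-derived neurotrophic factor, at 5.00-fold (log2 change 2.32 ± 0.254, adjusted p = 0.00839), from a mean log2 level of 8.89 ± 0.629 (n = 3) to 11.21 ± 0.413 (n = 6). Emcn, which encodes the endothelial sialomucin endomucin, rose 2.70-fold (1.43 ± 0.114, adjusted p = 0.00621), from 11.10 ± 0.227 to 12.53 ± 0.211. The largest fall among the genes named for this comparison was that of Esm1, which encodes endocan, a proteoglycan secreted by endothelial cells. Its signal was 4.14-fold lower in hypoxic lung (log2 change −2.05 ± 0.197, adjusted p = 0.00693), at 6.57 ± 0.358 (n = 6) against 8.62 ± 0.313 (n = 3). Genes were named in this comparison only if all 6 hypoxic arrays lay on the same side of the normoxic array of their strain.

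Among the other rises, Fzd4, a receptor for Wnt ligands and norrin in vascular endothelium, was 2.75-fold higher (log2 change 1.46 ± 0.325, adjusted p = 0.0456). Plxna4, a semaphorin receptor, was 2.72-fold higher (1.45 ± 0.226, adjusted p = 0.0179), and Sulf2, which removes sulfate from heparan sulfate chains, was 2.68-fold higher (1.42 ± 0.253, adjusted p = 0.0244). The transcription factor gene Mef2c rose 2.65-fold (1.41 ± 0.149, adjusted p = 0.00839), with 3 of its 4 other probe sets in the same direction. Gprin3 rose 3.50-fold, Rbx1, a subunit of cullin ubiquitin ligases, 2.89-fold, Rflnb 2.81-fold, Tex14 2.79-fold and Gas7 2.78-fold. Nipbl, the loader of cohesin onto chromosomes, rose 3.45-fold (1.79 ± 0.169, adjusted p = 0.00693) on its brightest probe set, but 2 of its 4 other probe sets went the opposite way.

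Among the other falls, Adipoq, the gene for the adipocyte hormone adiponectin, was 3.60-fold lower (log2 change −1.85 ± 0.401, adjusted p = 0.043), and Fabp4, a fatty acid binding protein of adipocytes and macrophages, was 2.80-fold lower (−1.48 ± 0.326, adjusted p = 0.0444). Ddr1, a receptor tyrosine kinase for collagen, was 3.92-fold lower (−1.97 ± 0.211, adjusted p = 0.00839), with 5 of its 6 other probe sets in the same direction. Aco1, which encodes cytosolic aconitase, an iron-regulated RNA-binding protein, was 3.28-fold lower (−1.71 ± 0.241, adjusted p = 0.0151). Tspan12, a partner of Fzd4 in norrin signalling, was 2.92-fold lower (−1.55 ± 0.223, adjusted p = 0.0166). The carboxylesterase gene Ces2b fell 3.82-fold, the proteasome subunit gene Psmc4 3.22-fold, Klhl2 3.17-fold, Mtfr1 2.80-fold and Akr1c14 2.79-fold. Dnajc17 fell 3.16-fold, while its other probe set did not move that way.

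**Figure D1:**
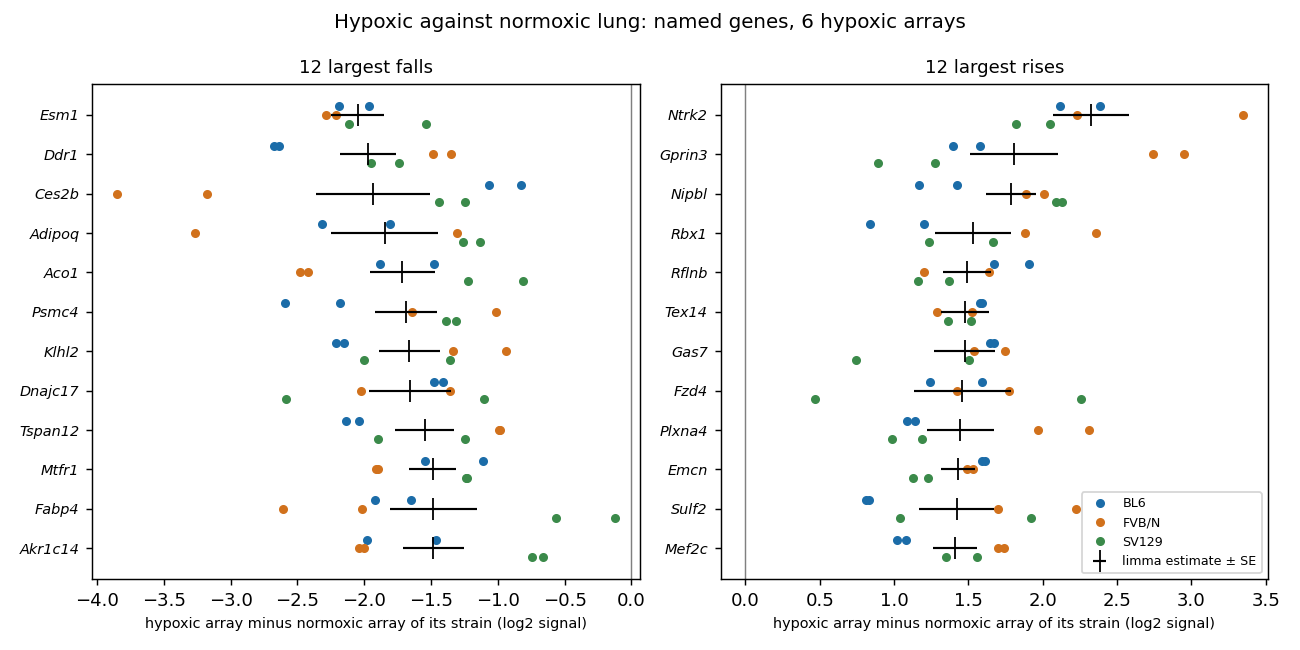
Log2 change of each hypoxic array from the normoxic array of its strain (points, coloured by strain) for the 12 largest falls and the 12 largest rises named for hypoxia, with the limma estimate ± SE over the 6 hypoxic arrays as black crosses. Genes were chosen to have all points on 1 side of 0, and the estimates run from −2.05 for Esm1 to 2.32 for Ntrk2.

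In all, 1016 of 27022 probe sets passed the threshold, 525 of them higher and 491 lower in hypoxic lung (51.7% higher). Of the genes read through their brightest probe set, 355 passed with the adjustment over all 27022 probe sets, and 183 (87 of them higher) when only those probe sets were tested. With each array centred on its median in place of quantile normalization, 1440 probe sets passed, 1027 higher and 413 lower (71.3% higher), and the median change over all probe sets was 0.11 in place of 0.04. The count fell to 401 without hypoxic BL6 array 2, to 32 without hypoxic BL6 array 5, to 321 and 299 without hypoxic FVB/N arrays 2 and 6, to 577 without hypoxic SV129 array 5, to 11 without the normoxic BL6 array and to 3 without the normoxic SV129 array. Without the normoxic FVB/N array 974 passed, but with 256 of them higher, and without hypoxic SV129 array 2 1390 passed, 806 of them higher. Other probe sets of the genes that passed moved in the same direction in 294 of 472 cases (62.3%). Of the 472, 35 also passed in the same direction and 9 passed in the opposite one. The median ratio of their change to that of the brightest probe set was 0.172. For the genes named above, 2 of 17 other probe sets of the rises and 2 of 12 of the falls passed in the same direction.

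Several measures besides condition and strain separated the arrays. Transcripts of kidney were abundant on hypoxic BL6 array 2 and on the normoxic FVB/N array. The mean log2 level of 21 kidney markers was 11.91 and 12.87 on these arrays, against 6.03 to 6.46 on the other 7. Umod, the gene for uromodulin, lay at 13.62 and 14.24 against a median of 5.56 on the other arrays, and Miox, the renal inositol oxygenase, at 13.66 and 14.34 against 4.69. A list of 8 brown adipocyte and fast skeletal muscle markers stood at 11.47 on the normoxic FVB/N array, against 6.28 to 7.81 on the others. The bacterial control transcripts bioB, bioC and bioD, which are added to every sample before hybridization, differed between conditions on all 7 of their probe sets. The signal of the 3′ bioC probe set was 2120 ± 291 on the 6 hypoxic arrays and 581 ± 21.6 on the 3 normoxic arrays (3.63-fold lower on these), and that of the 5′ bioD probe set was 6530 ± 1460 against 13500 ± 465, 2.11-fold higher on the normoxic arrays (2-sided exact permutation p = 0.0119 each, the smallest that 84 splits allow, Benjamini-Hochberg adjusted 0.0143 over 12 control probe sets).

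**Figure D2:**
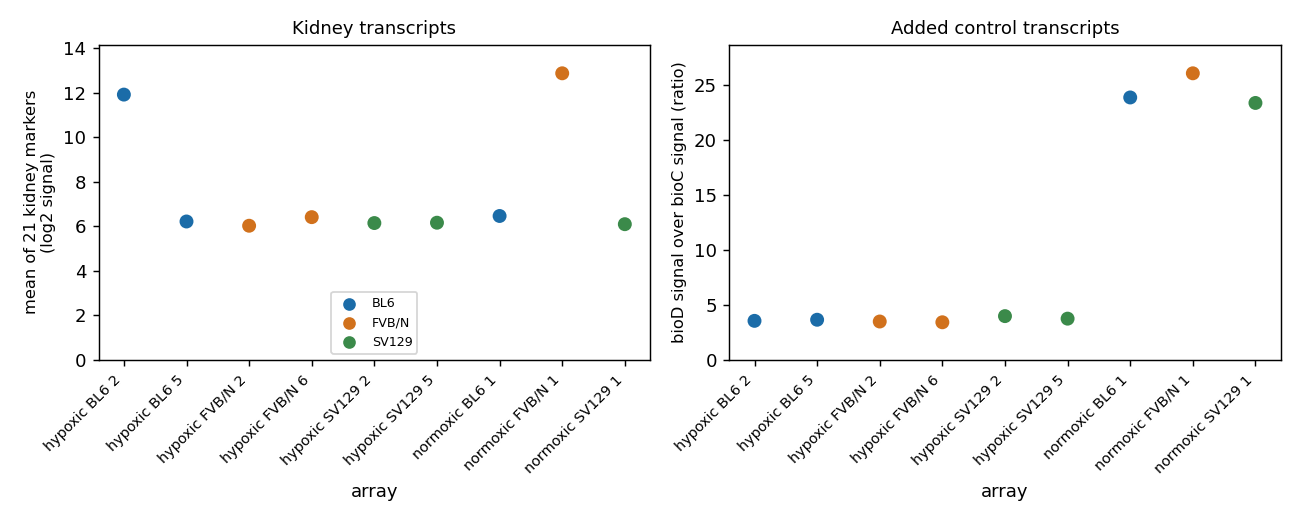
Left, mean log2 signal of 21 kidney markers on each of the 9 arrays, with hypoxic BL6 array 2 at 11.91 and the normoxic FVB/N array at 12.87. Right, signal of the added bioD control over that of bioC (a ratio) on each array, from 3.43 to 3.99 on the hypoxic arrays and from 23.4 to 26.1 on the normoxic arrays.

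Without the 2 arrays that carried kidney transcripts, 228 probe sets passed for hypoxia (37 higher and 191 lower), 160 of them shared with the 9-array result. Ntrk2, Emcn, Esm1, Mef2c, Ddr1, Aco1, Rflnb, Tex14, Psmc4, Klhl2, Mtfr1 and Tspan12 still passed without them. So did the probe set of Nipbl named above (1.71), but the probe set that was brightest for Nipbl on those 7 arrays had a change of −0.62 and did not pass. Gprin3 (log2 change 1.22), Rbx1 (1.36), Gas7 (1.35), Fzd4 (1.31), Plxna4 (1.09), Sulf2 (1.19), Ces2b (−1.14), Adipoq (−1.47), Dnajc17 (−1.69), Fabp4 (−1.01) and Akr1c14 (−1.24) did not.

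Of 22 extracellular matrix and remodelling genes tested, 7 rose, 0 fell and 15 did not pass over all probe sets, and 15 rose when adjusted over the list alone. Eln, the gene for elastin, rose 2.20-fold (log2 change 1.14 ± 0.145, adjusted p = 0.0138), Col1a1, a chain of fibrillar collagen I, 1.91-fold (0.93 ± 0.164, adjusted p = 0.0236), and Mfap4, a microfibril-associated glycoprotein, 1.81-fold (0.86 ± 0.136, adjusted p = 0.0185). The basement membrane collagen genes Col4a1 and Col4a2 rose by log2 changes of 0.67 and 0.58, the elastin cross-linking enzyme gene Loxl1 1.58-fold and the gelatinase gene Mmp2 1.55-fold. The list as a whole had a median log2 change of 0.45, with 21 members higher and 1 lower (limma camera with a preset correlation of 0.01, adjusted p = 4.04e-08; adjusted p = 0.605 with an estimated correlation; fry, adjusted p = 0.0268). Without the 2 arrays with kidney transcripts the median was 0.29 (camera, adjusted p = 3.65e-06; adjusted p = 0.73 with an estimated correlation) and 1 member rose.

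**Figure D3:**
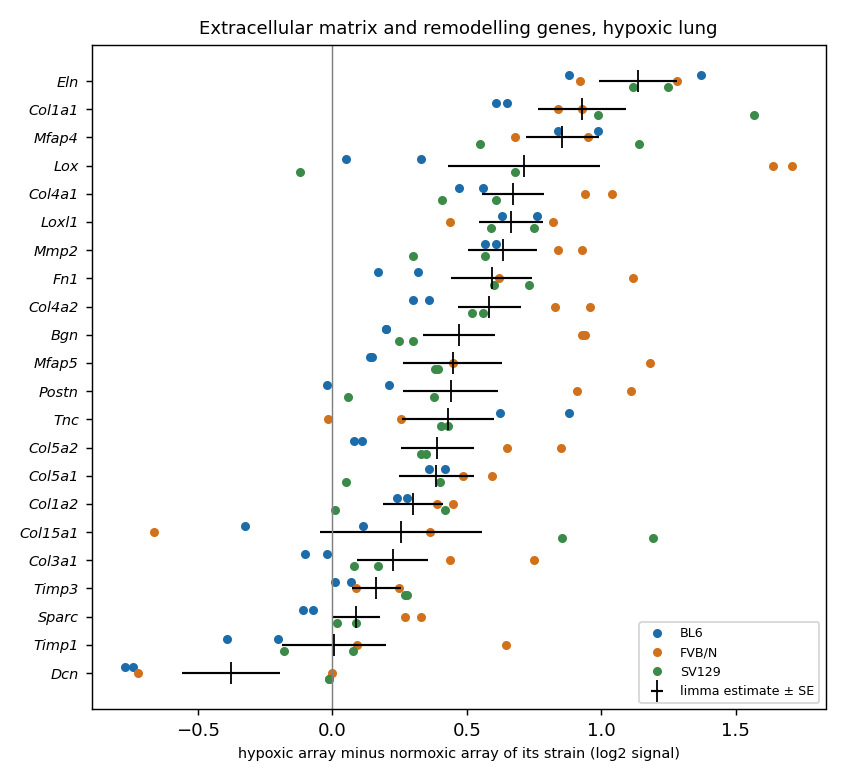
Log2 change of each hypoxic array from the normoxic array of its strain (points, coloured by strain) for the 22 extracellular matrix and remodelling genes tested, with the limma estimate ± SE as black crosses. 21 of the 22 estimates lie above 0, from −0.38 for Dcn to 1.14 for Eln.

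Smooth muscle contractile genes lay higher as a list, with 14 of 15 members above 0 and a median log2 change of 0.38 (camera, adjusted p = 0.00656; adjusted p = 0.738 with an estimated correlation). Of its members 1 rose, Tpm1, a tropomyosin (log2 change 0.58 ± 0.131, adjusted p = 0.0467), 0 fell and 14 did not pass, and 2 rose adjusted over the list alone, Tpm1 and Tagln (0.60 ± 0.162). Acta2, smooth muscle actin, had a change of 0.28 ± 0.139 and did not pass (adjusted p = 0.271). The list did not pass without the normoxic FVB/N array (adjusted p = 0.304), without both arrays with kidney transcripts (0.0675), with array weights (0.142) or with the mean of all probe sets of a gene (0.0819).

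Heart and skeletal muscle markers lay lower, with 20 of 20 members below 0 and a median log2 change of −0.37 (camera, adjusted p = 0.000524; adjusted p = 0.738 with an estimated correlation), though 0 of the 20 passed singly in limma, over all probe sets or adjusted over the list alone. The atrial peptide gene Nppa had a change of −1.41 ± 0.782 and skeletal actin, Acta1, one of −2.58 ± 0.959. The list of 8 brown adipocyte and fast skeletal muscle markers gave a camera p of 1.66e-05 (p = 0.139 with an estimated correlation), and the kidney list one of 0.006 (p = 0.532 with an estimated correlation). Both lists were put together after their markers had been seen on these arrays, so they are not independent evidence. The heart and skeletal muscle list did not pass without the normoxic BL6 array (adjusted p = 0.069) or without both arrays with kidney transcripts (adjusted p = 0.426).

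The neutrophil, erythroid, adipocyte and circadian clock lists also lay lower. Of 11 neutrophil markers 0 rose, 0 fell and 11 did not pass, and 2 fell adjusted over the list alone, the granule genes Ngp (−1.42 ± 0.369) and Ltf (−1.34 ± 0.398). The list's median was −0.43 (camera, adjusted p = 0.0199; adjusted p = 0.605 with an estimated correlation), and it did not pass without the normoxic SV129 array (adjusted p = 0.0819). Of 8 erythroid markers 1 fell, the haemoglobin gene Hbb-b2, by 2.14-fold (log2 change −1.10 ± 0.213, adjusted p = 0.0307), also adjusted over the list alone. The erythroid median was −0.25 (camera, adjusted p = 0.0363; adjusted p = 0.605 with an estimated correlation), with adjusted p = 0.069 without the normoxic BL6 array, 0.278 without the normoxic FVB/N array and 0.332 without both arrays with kidney transcripts, where Hbb-b2 did not pass either (−1.13, adjusted p = 0.121).

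Of 8 adipocyte markers 1 fell, Adipoq, and 7 did not pass, while 4 fell and 1 rose adjusted over the list alone. Car3, an abundant carbonic anhydrase of fat and muscle, had a change of −3.31 that did not pass over all probe sets (adjusted p = 0.0577). The adipocyte median was −0.51 (camera, adjusted p = 0.0363; adjusted p = 0.674 with an estimated correlation), and the list did not pass without hypoxic BL6 array 2 (adjusted p = 0.0612), hypoxic SV129 array 5 (0.0622), the normoxic BL6 array (0.195), the normoxic FVB/N array (0.093) or both arrays with kidney transcripts (0.17). Of 18 clock genes 0 rose and 0 fell in limma, over all probe sets or adjusted over the list alone. The clock median was −0.51 (camera, adjusted p = 0.0363; adjusted p = 0.674 with an estimated correlation), and the list did not pass without hypoxic BL6 array 2 (adjusted p = 0.0501), hypoxic SV129 array 5 (0.0622) or the normoxic BL6 array (0.191).

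These 7 of 23 lists passed with the preset correlation, 0 with an estimated correlation and 1, the matrix list, with fry. Without the normoxic BL6 array 3 lists passed, without the normoxic FVB/N array 4, and without both arrays with kidney transcripts 3. At least as many lists passed in 34 of 81 splits of the arrays into 6 and 3.

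Genes known to be induced by acute hypoxia did not pass after 4 weeks, the only exposure measured. Of 24 targets of the hypoxia-inducible factors and glycolytic enzymes 0 passed in limma, over all probe sets or adjusted over the list alone. The list median was −0.15 (camera, adjusted p = 0.306), and 0.03 without both arrays with kidney transcripts. The highest mean level of this list was on the normoxic FVB/N array (10.513). Vegfa had a change of −0.13 ± 0.182, Slc2a1, the glucose transporter Glut1, one of −0.50 ± 0.15 (adjusted p = 0.0995), and Adm, adrenomedullin, one of 0.77 ± 0.572. Of 21 cell cycle genes 0 passed over all probe sets and 3 rose adjusted over the list alone, Cdk1 (0.77 ± 0.207), Bub1b (1.06 ± 0.255) and Pcna (0.43 ± 0.104), with a camera adjusted p of 0.156. Of 22 vascular tone and pulmonary hypertension genes 0 passed, and 5 rose adjusted over the list alone: the endothelin-converting enzyme Ece1 (0.70 ± 0.186), endothelial nitric oxide synthase, Nos3 (0.75 ± 0.2), the soluble guanylate cyclase subunit Gucy1a1 (0.49 ± 0.144), angiotensin-converting enzyme, Ace (0.61 ± 0.19), and Ddah2 (0.72 ± 0.176). That list as a whole did not pass (camera, adjusted p = 0.391). Its median log2 change was 0.67 in FVB/N, against −0.09 in BL6 and −0.03 in SV129, and −0.09 without both arrays with kidney transcripts. The lowest mean level of this list was on the normoxic FVB/N array (10.023), which carried kidney transcripts. These medians are of the whole list and do not show which strain carries the 5 rises.

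Single members of other lists passed. Among 22 BMP and TGF-beta signalling genes Tgfb2 rose 1.59-fold (log2 change 0.66 ± 0.137, adjusted p = 0.0369) and Id2 fell 2.45-fold (−1.29 ± 0.153, adjusted p = 0.0105), with 2 rises and 1 fall adjusted over the list alone. Klf2, a transcription factor induced by shear stress in endothelium, rose 1.71-fold among 22 immediate early genes (0.77 ± 0.163, adjusted p = 0.0396), and 2 rose adjusted over the list alone, Klf2 and Gadd45b. Fkbp5, a glucocorticoid-induced chaperone, fell 2.51-fold among 15 glucocorticoid and stress genes (−1.33 ± 0.219, adjusted p = 0.0196), as it did adjusted over the list alone. The mucin gene Muc5b fell 2.69-fold among 15 airway epithelial markers (−1.43 ± 0.286, adjusted p = 0.034), as it did adjusted over the list alone. The camera adjusted p was 0.306 for the BMP and airway lists, 0.731 for the immediate early genes and 0.32 for the glucocorticoid list. Without both arrays with kidney transcripts Id2 still fell (−1.15), while Klf2 (0.69), Fkbp5 (−1.37) and Muc5b (−1.39) did not pass. On those 7 arrays another probe set was the brightest for Tgfb2, and it did not pass (0.09).

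Of the lists of resident cell types, 19 endothelial markers held 1 rise, Emcn, with 2 adjusted over the list alone, Emcn and Nos3 (camera, adjusted p = 0.137), and 18 macrophage and dendritic cell markers held 1 fall, Fabp4, with 2 adjusted over the list alone, Fabp4 and Cd163 (adjusted p = 0.32). Among 12 alveolar type 2 markers (adjusted p = 0.32) and 10 type 1 markers (adjusted p = 0.731) 0 passed over all probe sets, and Sftpd and Hopx each rose adjusted over the list alone. The 12 B cell markers (adjusted p = 0.23, with Jchain lower adjusted over the list alone), 14 T and NK cell markers (0.731), 19 interferon response genes (0.32) and 11 MHC genes (0.12) held 0 calls over all probe sets in limma, and the last 3 of these lists held 0 adjusted over the list alone too. Of 5 sex-linked genes 0 passed over all probe sets, with 2 higher (Xist and Kdm6a) and 2 lower (Eif2s3y and Kdm5d) adjusted over the list alone. Members of this list are expected to move in opposite directions where the sexes differ, so its camera test (adjusted p = 0.942) does not address a difference in sex between the conditions, and the labels do not give the animals' sex. Over the 9 arrays the log2 level ran from 9.31 to 10.92 for the Y-linked gene Eif2s3y and from 6.20 to 8.06 for Xist.

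The title of the series names a strain-specific response, so each strain was tested alone and the strains were then compared. In FVB/N lung 1837 probe sets passed, 797 higher and 1040 lower in hypoxia. Of the rises named by the rule, Gprin3 was 7.21-fold higher (log2 change 2.85 ± 0.297), Ntrk2 6.91-fold (2.79 ± 0.424) and Bace1, the beta-secretase, 6.76-fold (2.76 ± 0.395, with 2 other probe sets of the gene in the opposite direction). Rnf39 and Aplf lay at 4.52 and 4.68 on the normoxic FVB/N array, near the floor of 4 set by the constant added to each signal, so no fold is given for them. On the hypoxic FVB/N arrays Rnf39 lay at 7.77 and 7.62 (adjusted p = 0.0212) and Aplf at 7.47 and 7.26 (adjusted p = 0.0256). The falls named by the rule were those of Slco1a6 (adjusted p = 0.0336), the organic anion transporter Slc22a6 (adjusted p = 0.0367), Cyp4a12a (adjusted p = 0.0212), Slco1a1 (adjusted p = 0.0361) and Amn (adjusted p = 0.0406). Their log2 levels on the normoxic array were 12.95, 12.65, 12.33, 12.63 and 12.02. On the hypoxic FVB/N arrays they lay between 4.13 for Amn and 5.24 for Slco1a1, near the same floor, so no fold is given and the falls are not ranked. Slc22a6 is 1 of the kidney markers. Each of these genes also lay higher on hypoxic BL6 array 2, which carried kidney transcripts, than on hypoxic BL6 array 5. In the same order the levels were 9.87, 10.3, 8.24, 8.91 and 10.35 against 5.08, 5.27, 6.10, 4.25 and 5.43. Their falls in FVB/N cannot be told apart from kidney transcripts on the normoxic array. The FVB/N comparison rests on the 1 normoxic array that carried kidney and muscle transcripts, and no value exists without it.

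Of the 1040 probe sets lower in hypoxic FVB/N lung, 277 (26.6%) were also more than 1 log2 unit higher on hypoxic BL6 array 2 than on array 5, against 692 of all 27022 (2.56%) and 0 of the 797 higher ones. Without hypoxic FVB/N array 2 or array 6 the FVB/N count was 0, and without hypoxic SV129 array 2 or 5 it was 3843 or 3789.

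In BL6 lung 4 probe sets passed, all of them lower, and the 1 gene named through them was Ddr1, 6.29-fold lower (log2 change −2.65 ± 0.228, adjusted p = 0.0396). Of the 6 other probe sets of Ddr1, 0 passed in BL6, with 5 lower and 1 higher. At an unadjusted p under 0.05, 3371 probe sets passed in BL6. The BL6 count was 0 without hypoxic BL6 array 2, hypoxic FVB/N array 2 or hypoxic FVB/N array 6, 207 without hypoxic BL6 array 5, 130 and 161 without hypoxic SV129 arrays 2 and 5, and 17 without the normoxic FVB/N array. Without hypoxic BL6 array 5 the only hypoxic BL6 array left was array 2, which carried kidney transcripts. Most calls were then higher, while all in the main setting were lower. The count for that setting cannot be told apart from kidney transcripts. In SV129 lung 0 probe sets passed in limma and 2047 did at an unadjusted p under 0.05. The smallest p-values in SV129 belonged to Nipbl (2.11 ± 0.223), Ddr1 (−1.84 ± 0.228), Emcn (1.18 ± 0.161), Mef2c (1.45 ± 0.215) and Mospd2 (−1.34 ± 0.221), each with an adjusted p of 0.356.

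Within each strain the matrix list had a positive median, 0.22 in BL6 (camera, adjusted p = 0.00843; adjusted p = 0.78 with an estimated correlation), 0.78 in FVB/N (8.63e-06; adjusted p = 0.26 with an estimated correlation) and 0.36 in SV129 (1.22e-09; adjusted p = 0.126 with an estimated correlation). The heart and skeletal muscle list had a median of −0.88 in BL6 (1.14e-05; adjusted p = 0.784 with an estimated correlation) and of −0.46 in FVB/N (0.00471; adjusted p = 0.773 with an estimated correlation), against 0.06 in SV129 (adjusted p = 0.952). In BL6 Nppa had a change of −3.89. Lists that passed in 1 strain or more also included T and NK cell markers, with a median of 0.70 in FVB/N (0.0104) and −0.63 in SV129 (0.0118), neutrophil markers in SV129 (−0.75, adjusted p = 9.93e-05, against 0.17 in FVB/N, where they did not pass) and cell cycle genes in SV129 (0.20, 0.0155). For the neutrophil list the difference in response between FVB/N and SV129 did not pass (camera with the preset correlation, adjusted p = 0.494). Its mean level in FVB/N was 8.664 and 9.345 on the hypoxic arrays, against 9.401 on the normoxic array. The smooth muscle list passed in FVB/N (0.71, 0.000212) and SV129 (0.33, 0.0435). In FVB/N alone the endothelial (0.79, 0.000105), MHC (0.47, 0.00983), BMP and TGF-beta (0.61, 0.0188), vascular tone (0.67, 0.022), alveolar type 1 (0.36, 0.0227), B cell (0.75, 0.0238) and erythroid (−0.51, 0.03) lists passed, and in BL6 alone the clock (−1.11, 0.0087), adipocyte (−1.12, 0.0087) and macrophage (−0.27, 0.0121) lists. Values in brackets are medians and camera adjusted p-values, and with an estimated correlation 0 of these lists passed in any strain (the smallest adjusted p with an estimated correlation was 0.396 for these). The median change over all probe sets was 0.17 in FVB/N, 0.02 in BL6 and 0.01 in SV129. The FVB/N values rest on the normoxic array with kidney and muscle transcripts. On it the matrix, smooth muscle, endothelial, MHC and B cell lists had their lowest mean level of the 9 arrays. So did the BMP and TGF-beta, vascular tone and alveolar type 1 lists, while the T and NK list did not. The endothelial mean was 11.47 there, against 11.72 to 12.27 on the others. Rises of these lists in FVB/N cannot be told apart from a difference of that array.

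The difference between strains in the response was tested itself. In limma's F test of the interaction 0 probe sets passed, 3328 did at an unadjusted p under 0.05, and the smallest adjusted p was 0.208. The genes with the smallest p were Mylpf, Ccl28, Acy1, Mal and Tnni2. Mylpf and Tnni2, components of fast skeletal muscle fibres, had changes of −4.40 ± 0.308 and −5.64 ± 0.446 in FVB/N, against 0.24 and −0.38 in BL6 and 0.34 and −0.85 in SV129. Ccl28, a mucosal chemokine, had −5.02 ± 0.397 in FVB/N, −0.09 in BL6 and −0.11 in SV129, Acy1 had −4.96, 1.09 and −0.22, and Mal had −2.36, 0.89 and 0.67. On the normoxic FVB/N array, which carried kidney and muscle transcripts, Mylpf lay at 11.17, Tnni2 at 11.9, Ccl28 at 11.48 and Acy1 at 12.26. On the other arrays they reached at most 7.19, 6.93, 6.845 and 8.66. Mal lay at 11.31, against up to 11.16 on the others. These FVB/N changes rest on that 1 normoxic array and cannot be told apart from what it carried. Leaving out either hypoxic BL6 array takes the difference within that pair, kidney transcripts included, out of the spread. The normoxic FVB/N array, which carried kidney transcripts too, stays in the interaction. Interaction counts from such fits cannot be told apart from kidney transcripts. The interaction count was 241 without hypoxic BL6 array 2, which carried kidney transcripts, and 607 without hypoxic BL6 array 5.

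Of 69 tests of a list's difference in response between a pair of strains, 24 passed with the preset correlation and 0 with an estimated correlation, where the adjusted p was 0.569 or more. Across 27022 probe sets, which are not independent replicates, the log2 changes of BL6 and SV129 had a Pearson correlation of 0.521 (Spearman 0.523), those of FVB/N and SV129 one of 0.255 (0.324) and those of BL6 and FVB/N one of −0.097 (0.162). The last was 0.243 without hypoxic BL6 array 2 and −0.335 without hypoxic BL6 array 5, and that of FVB/N and SV129 was 0.146 without hypoxic SV129 array 5. Each change is measured from a normoxic array, and all of these differed from the hypoxic arrays in the added control transcripts. The correlations can thus hold a shared difference in processing and do not by themselves show a shared response to hypoxia. Kidney transcripts lay on a hypoxic array in BL6 and on the normoxic array in FVB/N, which moves their changes in opposite directions. The SD of the log2 changes was 0.567 in BL6, 0.937 in FVB/N and 0.457 in SV129.

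The strains were then compared over both conditions. In BL6 lung Bpifa1, a secreted protein of the airway epithelium, stood at a mean log2 level of 11.03 ± 2.95 (n = 3), against 5.71 in FVB/N and 4.95 ± 0.191 in SV129, and the antibacterial lectin Reg3g at 9.62 ± 1.77 against 5.08 ± 0.556 and 4.21 ± 0.0599. Sox11 exceeded both other strains by at least 4.92 log2 units and Nxpe4 by at least 4.18. Lower in BL6 than in both others were Tmem87a, at 5.60 ± 0.853 against 10.71 ± 0.196 and 10.55 ± 0.58, Gdpd3, the antitrypsin gene Serpina1b and Tnfrsf14, the herpesvirus entry mediator. In FVB/N lung Ms4a4b, a membrane protein of T cells, stood at 4.46 ± 0.437 against 10.25 ± 0.156 in BL6 and 10.68 ± 0.231 in SV129, and Mndal and C920006O11Rik were lower too. The MHC class II chain H2-Eb1 was lower in FVB/N, at 8.72 ± 0.337 against 13.32 ± 0.0931 and 12.96 ± 0.207, while its partner chain H2-Ea was higher, at 9.30 ± 0.966 against 5.07 ± 0.187 and 5.06 ± 0.433. AI506816, Rad51ap1 and the muscle gene Tmod4 were higher in FVB/N as well.

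In SV129 lung BC018473 stood at 9.97 ± 0.244, against 4.33 ± 0.065 in BL6 and 4.28 ± 0.0559 in FVB/N, and the guanylate-binding protein gene Gbp2b at 10.23 ± 0.131 against 5.82 ± 0.0859 and 5.11 ± 0.505. Pam, the peptide-amidating enzyme, and Rbm45 were also higher in SV129. Ppbp, a platelet chemokine, was lower in SV129, at 7.63 ± 0.483 against 11.38 ± 0.192 and 12.10 ± 0.264, as were Efhd2, Cldn34c1 and Tmem267. A sequence difference under a probe lowers its signal in the strain that carries it, so a strain difference read from 1 probe set is not by itself a difference in transcript level.

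**Figure D4:**
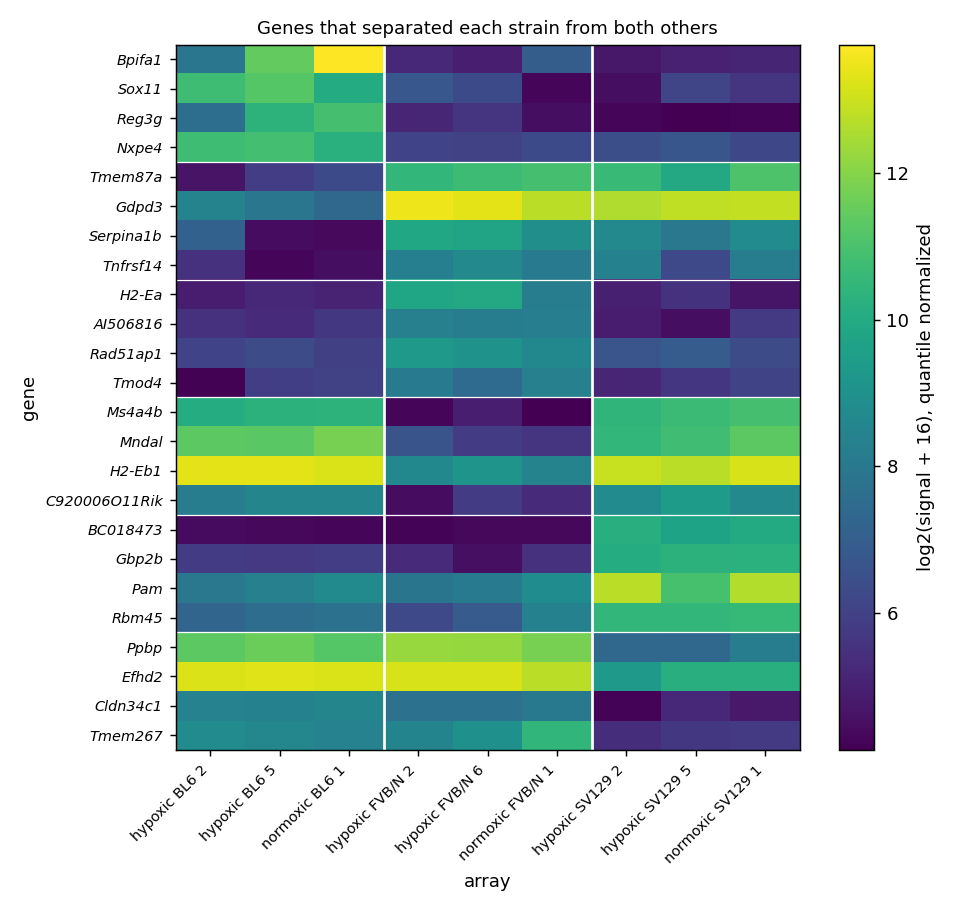
Log2 signal (colour) on each of the 9 arrays for the 24 genes named for the strain comparison, grouped by strain and direction and divided by white lines. The gene BC018473 runs at about 9.97 on the SV129 arrays and at 4.33 and 4.28 on the BL6 and FVB/N arrays.

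The F test between strains passed for 1144 probe sets. Between BL6 and FVB/N 560 passed (412 higher in BL6), between BL6 and SV129 678 (364 higher in BL6) and between FVB/N and SV129 780 (286 higher in FVB/N). Genes higher than in both other strains numbered 63 in BL6, 18 in FVB/N and 55 in SV129, and genes lower than in both others 35, 97 and 56. The F count was 539 without hypoxic BL6 array 5 and 584 without the normoxic SV129 array. The count for BL6 against FVB/N was 251 without hypoxic BL6 array 5, 325 without hypoxic FVB/N array 2, 288 without the normoxic BL6 array and 323 without both arrays with kidney transcripts. That for BL6 against SV129 was 334 and 201 without hypoxic BL6 arrays 2 and 5, 388 and 410 without hypoxic SV129 arrays 2 and 5, 435 without the normoxic BL6, 1227 without the normoxic FVB/N and 281 without the normoxic SV129 array. That for FVB/N against SV129 was 470 without hypoxic BL6 array 5, 467 and 399 without hypoxic FVB/N arrays 2 and 6, 437 and 492 without hypoxic SV129 arrays 2 and 5, and 321 without the normoxic SV129 array.

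No list was tested as a whole between strains, so the following are counts of members past the threshold in the F test between strains. Of 18 macrophage and dendritic cell markers 6 differed. Marco, a scavenger receptor of alveolar macrophages, was lower in FVB/N than in SV129 (log2 difference −4.78 ± 0.322, adjusted p = 0.000147), and BL6 exceeded FVB/N by 2.51 ± 0.322 (adjusted p = 0.00417). For the chitinase-like gene Chil3 BL6 exceeded FVB/N by 2.13 ± 0.143 (adjusted p = 0.000121), and FVB/N lay below SV129 (−2.32 ± 0.143). Mrc1 and Retnla were also lower in FVB/N than in both other strains, and Cd68 and Cd163 lower than in BL6. Of 22 immediate early genes 7 differed. Egr1 lay lower in BL6 than in SV129 (log2 difference −3.70 ± 0.312, adjusted p = 0.000584), as did Fos (−2.92 ± 0.416, adjusted p = 0.00773), Egr2 (−2.48 ± 0.302) and Nr4a1 (−2.27 ± 0.391), along with Ccn1, Dusp1 and Zfp36.

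Of 15 airway markers 4 differed, all higher in BL6 than in both other strains. Besides Bpifa1 and Reg3g these were Scgb3a1, a secretoglobin, which in BL6 exceeded FVB/N by 4.02 ± 0.578 and SV129 by 4.45 ± 0.578, and Muc5b, by 2.64 ± 0.33 and 2.02 ± 0.33. Of 22 matrix genes 8 differed, among them Col1a1 (FVB/N minus SV129 −1.30 ± 0.19), Eln (−1.36 ± 0.167) and Tnc (−1.49 ± 0.197). Of 11 MHC genes 4 differed, H2-Ea, H2-Eb1, H2-Aa and H2-M3, the last lower in SV129 (BL6 minus SV129 2.05 ± 0.192). Of 11 neutrophil markers 3 differed (S100a8, Lcn2 and Csf3r), and of 14 T and NK cell markers 2 (Ccl5 and Nkg7).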

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

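The tests of kidney markers, of alveolar markers, of the added control transcripts and of the result without 2 arrays were chosen only after the result was seen, while those of other probe sets of a gene and of other splits of the arrays were fixed beforehand.

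Among the 6 hypoxic arrays, hypoxic BL6 array 2 lay far from the others for the mean log2 level of kidney markers, at 11.913 against 6.025 to 6.411 (the gap was 0.934 of the whole range, above the critical value for 6 arrays). This was 1 of 25 lists examined in this way, and chance alone sets apart about 1 group in 20. That rate does not apply to the kidney list, which was put together after its markers had been seen in these data. On that array and on the normoxic FVB/N array, 19 of 21 kidney markers lay more than 1 log2 unit above all other arrays, the exceptions being Lrp2 and Slc4a1, which is also on the erythroid list, and 210 probe sets were more than 2 log2 units above the other 7 arrays on both. A kidney sample in place of lung is argued against by the 22 alveolar markers, whose median difference from the other arrays was −0.0475 and −0.422. A strain or hypoxia effect in BL6 is argued against by the difference of 5.7 log2 units between the hypoxic BL6 arrays, against 0.386 and 0.015 for the pairs of FVB/N and SV129. Kidney RNA carried into these lung samples is a candidate explanation, while for FVB/N an effect of strain under normoxia cannot be told apart from it, since there was 1 normoxic FVB/N array.

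The added control transcripts differed between the normoxic and hypoxic arrays although they carry no information on the animals. The fold differences were 2.37, 2.99 and 2.46 for the 5′, middle and 3′ probe sets of bioB, 3.2 and 3.63 for those of bioC (all lower on the normoxic arrays), 2.11 and 1.81 for those of bioD (higher on the normoxic arrays) and 1.36 for the 3′ probe set of cre (lower), while the 5′ probe set of cre overlapped. The 18S ribosomal RNA probe sets were 39.4-fold (5′), 4.52-fold (middle) and 3.6-fold (3′) higher on the normoxic arrays.

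These values bear on the hypoxia comparison as a whole. What part kidney RNA on 2 arrays has in the count cannot be told: 228 probe sets passed without them, and the 100% of called probe sets that kept their direction decides nothing, since they were chosen on arrays that include the remaining 7. A grouping by chance is argued against, as the real split gave 1016 probe sets and the highest of the other splits 38, in 1 of 81 fitted splits. That is the smallest share these splits allow, so chance is not excluded. Of the splits, 27 took 1 array from each strain, as the real one does, and the highest other count among them was 0. A different processing of the normoxic arrays may account for part of the calls: 7 of 7 bioB, bioC and bioD probe sets separated the conditions with no overlap, and other probe sets of the called genes moved the same way in 62.3% of cases, against 81.5% to 86.1% for the strain pairs. All normoxic arrays lay on one side of this difference, so processing and hypoxia cannot be told apart here, and an effect of hypoxia stays open beside it.

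For the strain comparison chance is argued against, with 1144 probe sets for the real grouping and 180 for the highest other, in 1 of 94 fitted splits. For pairs of strains there are too few splits (10) for a share under 0.05; the real grouping was the highest in 1 of 10 for each pair, and the real and highest other counts were 560 and 0 for BL6 against FVB/N, 678 and 2 for BL6 against SV129, and 780 and 0 for FVB/N against SV129. For the number of lists past the threshold for hypoxia chance cannot be excluded, since 34 of 81 splits gave 7 or more and the highest other gave 13. For the matrix list the real camera p was 1.75e-09, as small a value came up in 4 of 81 splits, and the smallest of the others was 1.16e-11.

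Differences between strains in a list's response to hypoxia passed the preset-correlation test for the following lists, and none of them with an estimated correlation. Each value is the median, over the members of the list, of the difference between the log2 changes of the strains. For BL6 minus FVB/N, where the median over all probe sets was −0.206, they were −0.39 for matrix, −0.723 for smooth muscle, −0.626 for endothelial, −0.41 for alveolar type 1, −0.823 for T and NK cell, −0.43 for BMP and TGF-beta and −0.663 for vascular tone genes. For BL6 minus SV129 they were −0.133 for matrix, −0.165 for smooth muscle, 0.33 for endothelial, −0.211 for macrophage, 0.563 for neutrophil, 0.48 for T and NK cell, −0.908 for heart and skeletal muscle and −0.719 for adipocyte genes. For FVB/N minus SV129, where the median over all probe sets was 0.169, they were 0.498 for smooth muscle, 0.926 for endothelial, 0.44 for alveolar type 1, 0.71 for B cell, 1.19 for T and NK cell, 0.739 for MHC, −0.494 for heart and skeletal muscle, 0.43 for BMP and TGF-beta and 0.598 for vascular tone genes. Values that involve FVB/N rest on its 1 normoxic array. There the lists given for FVB/N, except T and NK cell and heart and skeletal muscle, had their lowest mean level of the 9 arrays.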

How the results depend on the processing

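The values as the authors scaled them, those without the 2 arrays with kidney transcripts and those with the kidney marker level as a covariate were chosen after seeing the data, and all other alternatives were planned. Over all alternatives 192 of 280 counts and correlations stayed within their limits and 88 moved. Of 161 values for the lists that passed, 123 stayed past the threshold and 38 did not. Of 1381 values for named genes 1155 kept their side of the threshold, 213 lost it, 13 gained it and 0 reversed. The absence of reversals decides nothing, since the named genes were chosen for their changes on these same arrays. The SV129 count was 0 under each alternative that gave a value. The cause was not tested.

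For hypoxia across strains the 1016 probe sets became 582 with no filter, 657 without a trend, 1871 with array weights, 183 with only the brightest probe set of each gene tested (355 of these passed with the adjustment over all probe sets), 1606 as the mean of the 3 strain effects, 553 with no strain term, 228 without both arrays with kidney transcripts (7 arrays) and 1966 with the kidney covariate. Leaving out single arrays gave 3 to 1390. In BL6 the 4 became 17 with the dimmest 60% left out, 0 without a trend, 22 with robust eBayes, 463 with array weights, 0 without both kidney arrays and 0 with the covariate, and 0 to 207 with single arrays left out. In FVB/N the 1837 became 1087 with no filter, 5 without a trend, 0 with array weights and 0 with the covariate, and 0 to 3843 with single arrays left out. In each strain's model the slope of the covariate rests mostly on the hypoxic BL6 pair, whose kidney scores differ by 5.7 against 0.386 and 0.015 in the other pairs, so its counts of 0 do not bear on the cause. With it the FVB/N change of Ntrk2 was 3.19 and did not pass. The interaction count of 0 became 7 with a pseudocount of 64 and lay at 0 to 607 with single arrays left out.

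For strain differences the 1144 became 2687 with array weights, 532 with 1 probe set per gene and 745 on the 6 hypoxic arrays, and 539 to 1585 with single arrays left out. BL6 against FVB/N (560) gave 369 with the dimmest 60% left out, 2199 with array weights, 323 without both kidney arrays and 1025 with the covariate, and 251 to 748 with single arrays left out. BL6 against SV129 (678) gave 1291 with array weights and 436 on the 6 hypoxic arrays, and 201 to 1227 with single arrays left out. FVB/N against SV129 (780) gave 451 on the 6 hypoxic arrays, and 321 to 771 with single arrays left out.

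With the array number as a replicate block the strain count was 369, and the pairs gave 187 (BL6 against FVB/N), 299 (BL6 against SV129) and 181 (FVB/N against SV129), while the interaction count stayed at 0 and 21 interaction list tests passed. Whether the numbers pair the arrays was examined only for BL6 and SV129, where the deviations of arrays 2 and 5 from their group means had a correlation of −0.0422 over 27022 probe sets, and FVB/N array 2 was not compared. The block gave no value for hypoxia, since number 1 marks all normoxic arrays and no others. With a strain's normoxic array left out, that strain's effect and the interaction have no value either, and without both kidney arrays neither has the FVB/N effect.

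The 7 hypoxia lists became 0 with an estimated correlation, 1 with fry, 11 as the authors scaled the values and 3 without both kidney arrays, and 3 to 9 with single arrays left out. Besides these settings, the smooth muscle list was lost with array weights (adjusted p = 0.142) and with the mean of all probe sets of a gene (0.0819), the clock list with that mean (0.0819), the neutrophil list with array weights (0.112), the erythroid list with no filter (0.0596), array weights (0.0852) and the covariate (0.0569), and the adipocyte list with no filter (0.0596) and the dimmest 60% left out (0.262). The 24 interaction list tests became 15 with median centring and 0 with an estimated correlation. The correlation of BL6 and SV129 changes (0.521) was 0.33 with no filter and 0.644 with the dimmest 60% left out, and 0.414 to 0.537 with single arrays left out. That of FVB/N and SV129 (0.255) was 0.17 with no filter and 0.344 with the covariate, and 0.146 to 0.272 with single arrays left out, and that of BL6 and FVB/N (−0.097) lay at −0.335 to 0.243.

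Of 66 other probe sets of named genes 22 passed in the same direction or kept their side, 31 lost the call and 13 reversed. The reversed changes were −0.582 and −0.383 (Nipbl), −0.131 (Mef2c), 0.151 (Ddr1) and 0.0117 (Dnajc17) for hypoxia across strains, 0.00466 for Ddr1 in BL6, −0.628 and −0.0714 for Bace1 in FVB/N, and −0.325 and −0.894 (Nipbl), 0.139 (Ddr1), −0.305 (Mef2c) and 0.224 (Mospd2) in SV129.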

Other observations

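The tests on clock genes below were chosen only after the result was seen.

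Muc5b, which fell across strains, had log2 changes of −1.31 in BL6, −1.49 in FVB/N and −1.49 in SV129. Scgb3a1 had −1.10, −1.65 and −1.59 and did not pass across strains (limma, adjusted p = 0.136). For Bpifa1 the changes were −4.09 in BL6, −1.89 in FVB/N and −0.25 in SV129, and it did not pass across strains (adjusted p = 0.171) nor in the test of the interaction (adjusted p = 0.56). The abundant club cell genes Scgb1a1 (0.10 ± 0.0701) and Cyp2f2 (0.13 ± 0.0892) did not pass.

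Clock genes differed between arrays of one group. Dbp, a clock output gene, had log2 levels of 12.66 and 9.27 on hypoxic SV129 arrays 2 and 5 and 12.14 on the normoxic SV129 array, and Arntl, the partner of Clock, had 7.29, 9.75 and 8.49. In BL6, Dbp had 9.83 and 10.81 on the hypoxic arrays and 12.72 on the normoxic one, with Arntl at 9.72, 9.53 and 7.49. In FVB/N, Dbp had 12.89, 12.36 and 12.77. A score set from clock genes of opposite phase differed by 3.5 log2 units between the hypoxic SV129 arrays, which argues against a response to hypoxia alone. Collection at different times of day may account for it, but the correlation that was examined does not decide this. Over 18 clock genes the difference between the hypoxic SV129 arrays followed the change from normoxic to hypoxic BL6 with a Pearson r of 0.717 (Spearman 0.622). That was at the 99.5 percentile of 10000 random lists of that size, whose median r was 0.11. With hypoxic BL6 array 5 alone r was 0.685, below the bound of 0.7 set for this test. Clock genes shift as a set, which random lists need not do. Any shift of the clock, whatever its cause, could thus give a high r. The correlation is across genes, which are not independent replicates, and the labels used here give no time of collection.

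Of 88 genes with more than 1 probe set past the threshold for hypoxia, 17 had probe sets called in both directions, among them Eny2, Hnrnpf, Kdm5a and Rbm25. Probe sets whose name marks possible binding to several transcripts made up 30.5% of those higher, 58.9% of those lower and 25.7% of those not called. On hypoxic BL6 array 2, 31 of 37 probe sets that set BL6 apart from the other strains lay on the side of BL6, and on the normoxic FVB/N array 37 of 38 lay on the side of FVB/N.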
